A study of Homo sapiens with 6 samples.

How the data were processed

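RNA sequencing of T3M4 cells grown without treatment was analysed from the tables the authors deposited. Per the labels' protocols, RNA was taken with a column kit from cells near confluence and made into libraries with the NEBNext Ultra RNA kit, which does not mark strand. Per the submitters' processing notes, fastp, HISAT2, STAR and DESeq were used with the genome builds GRCh38 and hg38; their versions and roles, the counting tool and its strand setting are not given in the sources used here. Without strand, reads of a gene and of an antisense or overlapping gene cannot be told apart. All 58735 genes of the deposited count table have the ID, chromosome, start, end and strand of GENCODE release 29, so positions are on GRCh38.

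The main table holds raw read counts per gene and library as the authors deposited them, 1 column per library. A second table from the authors holds their comparison. Its count columns equal those of the main table for the 29015 genes it lists. Its normalised signal columns are counts that the authors divided by 1 factor per library, as the values show. Its FPKM columns, named per the file headers, are those normalised values divided by gene length and 1 constant shared by all libraries, and were not used here. Its log2 fold changes and its p-values are the authors' own, per the file headers, with the processing notes naming DESeq; they are quoted only as the authors' deposited table, in which an adjusted p of exactly 1 was given to 9002 genes and may stand for no value.

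Libraries were grouped by their titles and genotype labels into 3 labelled WT and 3 labelled MUC16 knockout. The name WT is from the titles, T3M4WT, and the genotype label of these libraries reads MUC16 expressing. The titles of the other group read T3M4M16 and do not say knockout, which is from the genotype label. Counts were tested with edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest, two-sided, group as the only term), with TMM factors and filterByExpr (minimum count 10, minimum total count 15), which left 16655 genes, 13429 of them protein-coding. P-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05, and a second count asked for at least 2-fold. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. Levels are TMM-scaled CPM, given as mean ± SD. Gene lists with at least 5 measured members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, correlation between genes 0.01), adjusted over the 36 lists, and again with the correlation estimated, which rests on 4 residual degrees of freedom, and with fry.

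The design, the tests, the alternatives, the 40 lists and the rule for naming genes were fixed before the data were examined. Named genes are MUC16; the 8 highest and 8 lowest log2 fold changes among protein-coding genes past the threshold with a mean of at least 100 normalised counts and groups that do not overlap; and up to 4 members of each list with the largest changes past the threshold, or the 2 with the smallest p where none passed. Other list members were named after their values were seen, to show which members did not follow the rest. Gene families by symbol, the chromosome comparison, cyclic loess, limma-trend with TMM factors and the fit without chromosome 5 were also chosen after the data were seen.

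Library totals ran from 19088927 to 28612621 counts, and the biological coefficient of variation was 0.0498. The edgeR step was tested on simulated counts with the means and library sizes of this comparison, over 16655 genes. It called 52% of genes changed 1.25-fold, 66% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, and 7 unchanged genes. The simulation changed only 50 genes at each fold and gave all genes the same dispersion. In the data 8759 genes were called, and the adjusted threshold depends on the share changed. These rates therefore check the step and do not carry over to this comparison. Libraries of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 2.41 to 6.21), so none was treated as a duplicate. Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a stricter filter (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, an adjusted p threshold of 0.01 and protein-coding genes alone.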

Results

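Gene-level RNA-seq counts were obtained for T3M4, an established human pancreatic ductal adenocarcinoma (PDAC) cell line. The 6 libraries fell into 2 groups of 3, one labelled WT and described as expressing MUC16, the other labelled MUC16 knockout. MUC16 is a very large membrane-tethered mucin of epithelial cells, and the comparison asks how the transcriptome of these cells differs with its loss. Total gene counts were 27127901, 27647455 and 22963814 in the libraries labelled WT and 19088927, 24909009 and 28612621 in those labelled knockout. Mitochondrial transcripts took 2.10% ± 0.142 of the counts in the libraries labelled WT and 2.09% ± 0.104 in those labelled knockout (SD, n = 3 each). Other measures separated the groups: ribosomal RNA genes took 0.133% ± 0.00785 in the libraries labelled WT and 0.159% ± 0.0097 in those labelled knockout, and protein-coding genes 98.26% ± 0.016 and 98.15% ± 0.0259. The 10 most abundant genes took 4.42% ± 0.0413 and 4.11% ± 0.0624, and the TMM factors averaged 0.973 and 1.03. Pearson correlations of log2 scaled counts (CPM) across genes were 0.992 to 0.993 within a group and 0.973 to 0.978 between groups. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

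MUC16 transcripts were higher, not lower, in the libraries labelled knockout. MUC16 (ENSG00000181143, GRCh38 chromosome 19, 8848844 to 8981342, minus strand) had 98, 144 and 90 counts in the libraries labelled WT and 292, 504 and 323 in those labelled knockout. Its level was 4.37 ± 0.866 CPM in the libraries labelled WT and 15.2 ± 4.29 CPM in those labelled knockout (SD, n = 3 each), a 3.45-fold difference. The log2 fold change of MUC16 was 1.79 ± 0.17 (SE, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.79e-09), and the authors' deposited table gives 1.78. The targeted gene thus went against the group labels at the RNA level, and every direction below is that of the libraries labelled knockout relative to those labelled WT. A count over the whole gene does not show which exons were read, so it cannot tell an edited from an unedited transcript.

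Among protein-coding genes with a mean of at least 100 normalised counts and groups that do not overlap, the largest rises were in ANGPTL4, a secreted inhibitor of lipoprotein lipase, and CA9, a membrane carbonic anhydrase. ANGPTL4 went from 1.53 ± 0.844 CPM in the libraries labelled WT to 20.6 ± 2.39 CPM in those labelled knockout (SD, n = 3 each, log2 fold change 3.72 ± 0.19, SE), and CA9 from 0.820 ± 0.419 to 8.14 ± 1.19 CPM (3.28 ± 0.22). ISLR2 (log2 fold change 3.02), the serine protease inhibitor SERPINB4, the membrane-associated protein PALM (2.98), matrilysin MMP7 (2.97), SPINK4 (2.83) and the arginine deiminase PADI2 (2.82) completed the 8 highest of these genes. The largest fall among them was in FOXJ1, a transcription factor of motile cilia, from 11.9 ± 0.952 CPM in the libraries labelled WT to 0.376 ± 0.0459 CPM in those labelled knockout (log2 fold change -4.97 ± 0.19, SE). Endothelin EDN1 (-2.50), the aldo-keto reductase AKR1B10 (-2.43), the metallothionein MT1E (-2.33), the IL-33 receptor IL1RL1 (-2.25), ANKRD1 (-2.24), SH2D5 (-2.23) and CTGF (-1.79) followed. Adjusted p-values of these 16 genes ran from 2.53e-17 for AKR1B10 to 3.23e-10 for CTGF (edgeR quasi-likelihood, Benjamini-Hochberg). SERPINB4, MT1E and AKR1B10 have near-identical relatives with which reads can be shared. ANGPTL4, CA9, SPINK4 and IL1RL1 overlap RAB11B-AS1, ARHGEF39, BAG1 and IL18R1, so their counts are uncertain to that extent.

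Across the transcriptome, 8759 of 16655 genes tested differed between the groups, 4442 higher and 4317 lower in the libraries labelled knockout (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p threshold 0.05). Changes of at least 2-fold were less even, with 1252 genes higher and 226 lower. With other single factors per library the split was 1245 and 232 (DESeq2 size factors) or 1375 and 188 (upper quartile). Cyclic loess, which scales by expression level and was chosen after the data were seen, gave 828 higher and 406 lower with limma-trend. Limma-trend with the TMM factors, added later, gave 1192 and 202, so the test alone did not move it. In the main fit the 2-fold rises lay mostly in weakly expressed genes. By mean level, 445 were higher and 98 lower under 1 CPM, 461 and 62 at 1 to 4 CPM, and 29 and 15 over 64 CPM. The median log2 fold change of all tested genes was 0.23 under 1 CPM, 0.26 at 1 to 4 CPM and -0.11 over 64 CPM. Of 899 antisense genes tested 180 were higher and 74 lower, of 814 lincRNA genes 225 and 59, and of 13429 protein-coding genes 3860 and 3976. The 3 values of one group lay wholly outside those of the other for 59.0% of the genes tested, where chance gives 10%. The authors' deposited table called 7500 genes, 3612 higher and 3888 lower. Of these, 7369 were also called here, all 7369 in the same direction, from the same counts.

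Of 40 gene lists fixed beforehand, 36 had at least 5 measured members, and 19 passed camera's test, 11 higher and 8 lower in the libraries labelled knockout. The plot of list members shows each gene. Camera was run with a preset correlation between genes. With the correlation estimated from these 6 libraries, 0 lists passed (lowest adjusted p = 0.128, 6 lists at an unadjusted p under 0.05). That version rests on 4 residual degrees of freedom. NRF2 targets (-0.00902), matrix proteases (-0.0373), O-glycosylation enzymes (-0.0237) and cholesterol synthesis (0.00924) had estimates below the preset 0.01 and lost their calls too. For these lists the loss does not show that correlation between genes gave the calls. The other called lists had estimates above 0.01, among them interferon-stimulated genes (0.482), hypoxia targets (0.325) and oxidative phosphorylation (0.315). For those the preset may be too low and its p-values too small. Fry, which tests whether a list's genes moved on balance one way and does not compare them with other genes, called 29 lists. Those it added were the MUC16 partners, mesenchymal genes, fatty acid synthesis, the unfolded protein response, DNA replication, MHC class I, cytokines, integrins, stem cell genes and immediate early genes. The estimated-correlation value is given beside each list that passed.

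**Figure D1:**
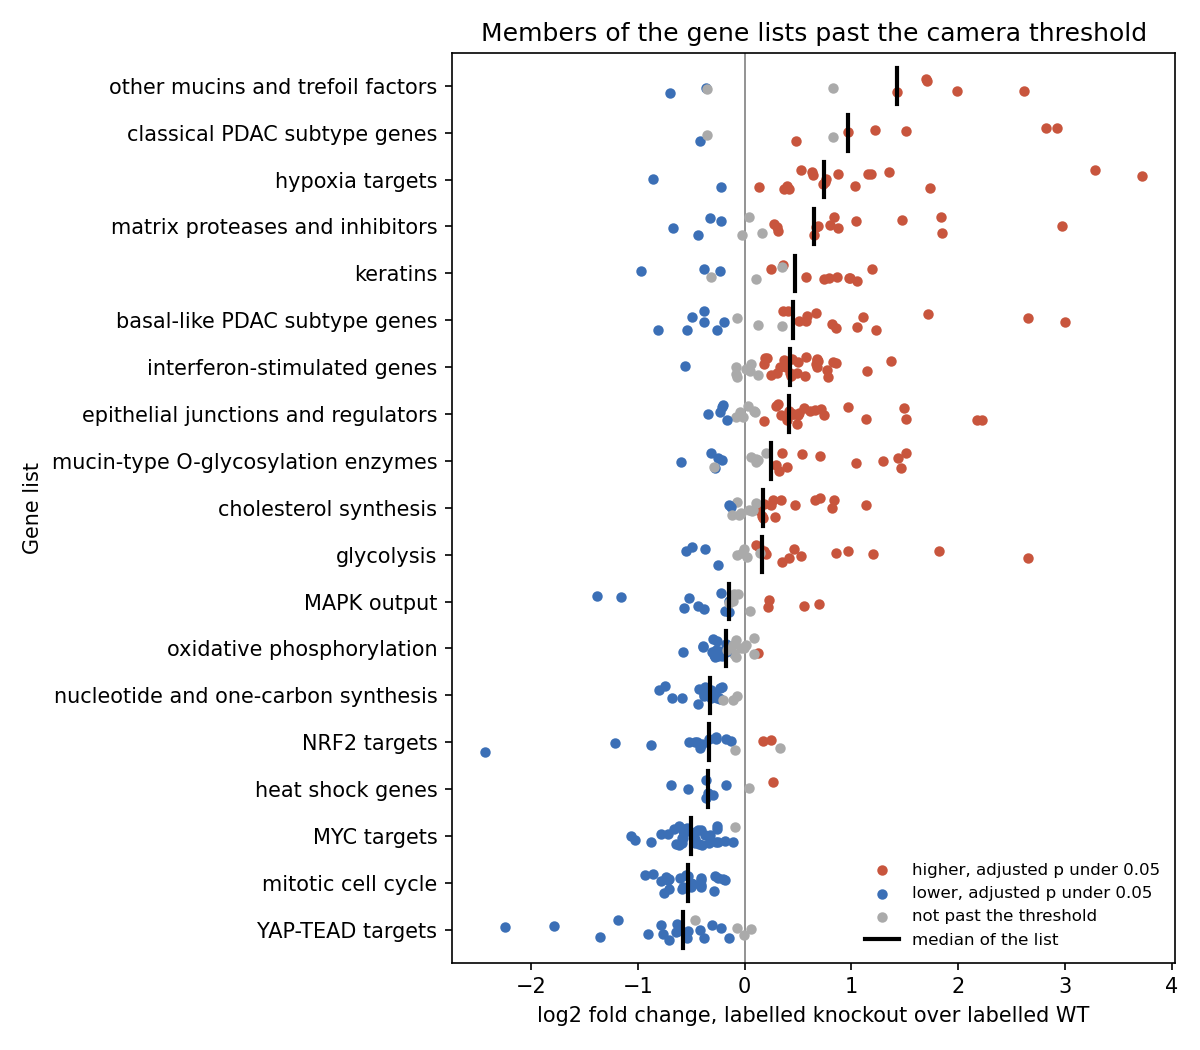
Log2 fold change (horizontal axis, labelled knockout over labelled WT, 3 libraries each) of every measured member of the 19 gene lists past camera's threshold, 1 point per gene, red for higher and blue for lower at an edgeR adjusted p under 0.05, grey otherwise, with the list median as a black bar. All 25 mitotic cell cycle genes lie to the left of 0, and 18 of 20 hypoxia targets to the right.

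Most other mucins rose together with MUC16. MUC1, a membrane mucin, went from 16.2 ± 1.93 to 99.2 ± 1.26 CPM (SD, n = 3 each, log2 fold change 2.61 ± 0.07, SE). MUC4 went from 5.88 ± 0.782 to 23.5 ± 6.51 CPM (1.99 ± 0.15), and MUC5B (1.71), MUC20 (1.70) and MUC13 (1.43) were also higher in the libraries labelled knockout. The gel-forming mucins MUC2 (-0.36) and MUC5AC (-0.70) fell. The trefoil factors TFF1 and TFF2 did not pass the test (0.83 and -0.35). Over the 9 measured members, 5 were higher and 2 lower, the same counts adjusted over the list alone (median 1.43, camera adjusted p = 0.0416, adjusted p = 0.35 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.0698), without KO replicate 2 (0.0516), without KO replicate 3 (0.0577) and in 4 of the other alternatives. Enzymes that build mucin-type O-glycans were 11 higher and 5 lower of 22, as when adjusted over the list alone (median 0.25, camera adjusted p = 0.0269, adjusted p = 0.26 with an estimated correlation). Among them were the sialyltransferase ST6GALNAC1 (1.51), GALNT12 (1.47), GALNT5 (1.44) and GCNT3, which went from 170.0 ± 9.83 to 416.3 ± 1.63 CPM. Reported partners of MUC16 did not pass as a list (7 higher and 2 lower of 12, 9 and 2 adjusted over the list alone, camera adjusted p = 0.0572, adjusted p = 0.283 with an estimated correlation). They did pass with upper-quartile factors (adjusted p = 0.0417), a stricter filter (0.045), limma-voom (0.0264) and cyclic loess (0.00333). Among them mesothelin, MSLN (0.67), galectin-3, LGALS3 (0.58), and ERBB2 (0.57) were higher.

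**Figure D2:**
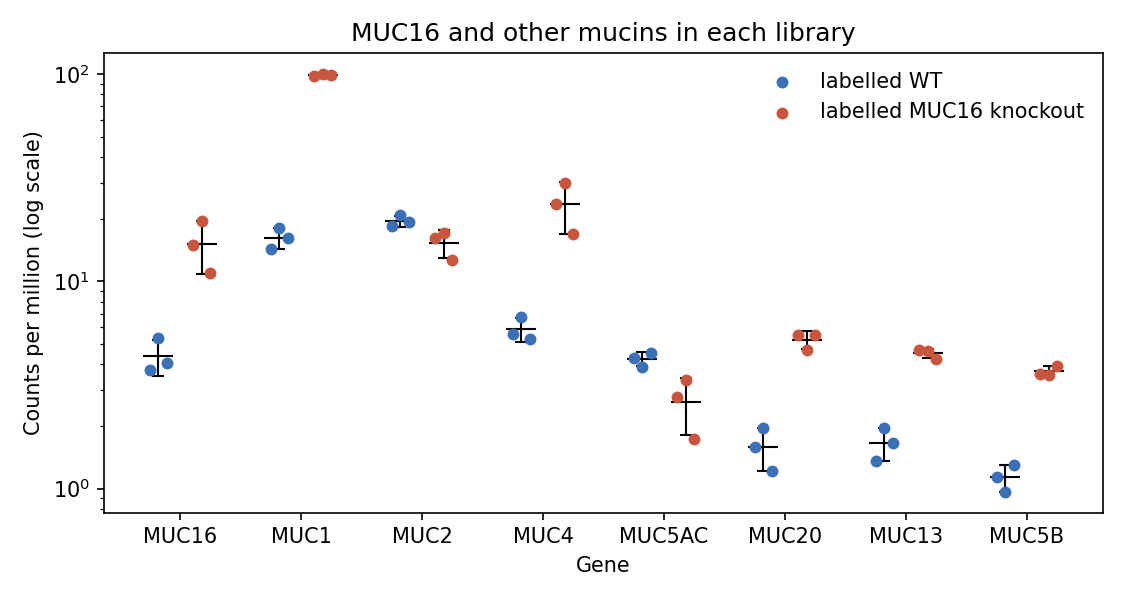
Scaled counts (CPM, vertical axis, log scale) of MUC16 and the other measured mucins in each of the 3 libraries labelled WT (blue) and the 3 labelled MUC16 knockout (red), with the group mean as a horizontal bar and 1 SD as error bars. MUC16 sits at 4.37 CPM on average in the libraries labelled WT and at 15.2 CPM in those labelled knockout, MUC1 at 16.2 and 99.2 CPM, and MUC2 and MUC5AC are lower in the libraries labelled knockout.

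Epithelial genes were mostly higher in the libraries labelled knockout. Of 33 junction genes and their regulators, 22 were higher and 5 lower (23 and 5 adjusted over the list alone, median 0.41, camera adjusted p = 9.22e-05, adjusted p = 0.273 with an estimated correlation). Among them were the tight junction scaffold TJP3 (2.22 ± 0.10, SE), the transcription factor ELF3 (1.51 ± 0.06), desmocollin DSC2 (1.49 ± 0.07) and E-cadherin, CDH1 (0.46 ± 0.04). Keratins were 10 higher and 3 lower of 16, also adjusted over the list alone (median 0.47, camera adjusted p = 0.0159, adjusted p = 0.261 with an estimated correlation). KRT16 (1.19) and KRT15 (1.05) had the largest changes of the list. KRT8 went from 737.4 ± 8.65 to 1453 ± 44.6 CPM and KRT13 from 275.3 ± 17.5 to 544.2 ± 12.4 CPM, while KRT5 fell (-0.98 ± 0.04, SE). Genes that mark the classical PDAC subtype were 6 higher and 1 lower of 9 (camera adjusted p = 0.0118, adjusted p = 0.337 with an estimated correlation), with SPINK4 (2.83) and ST6GALNAC1 (1.51) among the highest. LYZ rose most (2.93), but at a very low level, from 0.117 to 0.937 CPM. Only these 9 of the 23 classical genes were measured, against 24 of 25 basal-like genes, so most of the classical list was not tested. Basal-like subtype genes were 14 higher and 7 lower of 24 (camera adjusted p = 0.0269, adjusted p = 0.467 with an estimated correlation). The counts of both subtype lists were the same adjusted over the list alone. The classical call was lost with no filter (adjusted p = 0.109) and the basal-like call with a stricter filter (0.0571). SERPINB4, SERPINB3 (2.66), whose reads can be shared with SERPINB4, and the long non-coding RNA UCA1 (1.71) were the highest basal-like genes, and S100A2 (-0.81) was lower. Mesenchymal genes went both ways, 10 higher and 7 lower of 23, also adjusted over the list alone (camera adjusted p = 0.582). The collagens COL6A2 (2.19) and COL5A1 (1.45) were higher, SNAI2 (-0.69) was lower, and vimentin, VIM, did not pass (0.30).

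Mitotic genes and MYC targets were lower in the libraries labelled knockout. All 25 measured mitotic genes fell, also adjusted over the list alone, with a median log2 fold change of -0.53 (camera adjusted p = 5.3e-11, adjusted p = 0.128 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, went from 393.2 ± 5.7 to 205.8 ± 5.12 CPM and the proliferation marker MKI67 from 256.7 ± 16.6 to 152.0 ± 18.8 CPM (SD, n = 3 each). DNA replication genes did not pass camera as a list (3 higher and 6 lower of 23, also adjusted over the list alone, median -0.05, camera adjusted p = 0.371), with POLA1 (-0.46) lower and E2F1 (0.36) higher. MYC targets were 33 lower and 0 higher of 34, also adjusted over the list alone (median -0.51, camera adjusted p = 1.88e-12, adjusted p = 0.26 with an estimated correlation). TCOF1 (-1.06 ± 0.04, SE), the polyamine enzyme ODC1 (-1.03 ± 0.05) and NOP16 (-0.88 ± 0.07) fell most, and MYC itself by less (-0.19 ± 0.04). Nucleotide and one-carbon enzymes were 19 lower and 0 higher of 22, also adjusted over the list alone (median -0.32, camera adjusted p = 2.2e-07, adjusted p = 0.26 with an estimated correlation). IMPDH1 (-0.80), PFAS (-0.75) and CTPS1 (-0.68) were lowest. Oxidative phosphorylation genes were 17 lower and 1 higher of 28 (18 and 1 adjusted over the list alone, median -0.18, camera adjusted p = 0.000745, adjusted p = 0.467 with an estimated correlation). That call was lost with cyclic loess (adjusted p = 0.0553). Mitochondrially encoded genes did not pass (6 lower and 0 higher of 13, also adjusted over the list alone, camera adjusted p = 0.0676), except with no filter (adjusted p = 0.017), limma-voom (0.0237), without WT replicate 3 (0.0228) and without KO replicate 3 (0.0327).

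Several of these genes, TCOF1, NOP16, KIF20A, CCNB1 and SDHA among them, lie on chromosome 5, whose genes were lower as a whole. The median log2 fold change of its 781 tested genes was -0.20 against 0.01 for the other chromosomes, with 111 higher and 366 lower in the libraries labelled knockout. Chromosomes 6, 12 and 19, the last of which carries MUC16, were slightly higher than random gene lists, with medians of 0.08, 0.05 and 0.08. Chromosome 5 took 5.22% ± 0.0513 of the counts in the libraries labelled WT and 4.30% ± 0.0179 in those labelled knockout (SD, n = 3 each). Without the genes of chromosome 5, an alternative chosen after the data were seen, 19 lists passed, 17 of them as before. Glycolysis (adjusted p = 0.0508) and MAPK output (0.0745) did not.

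**Figure D3:**
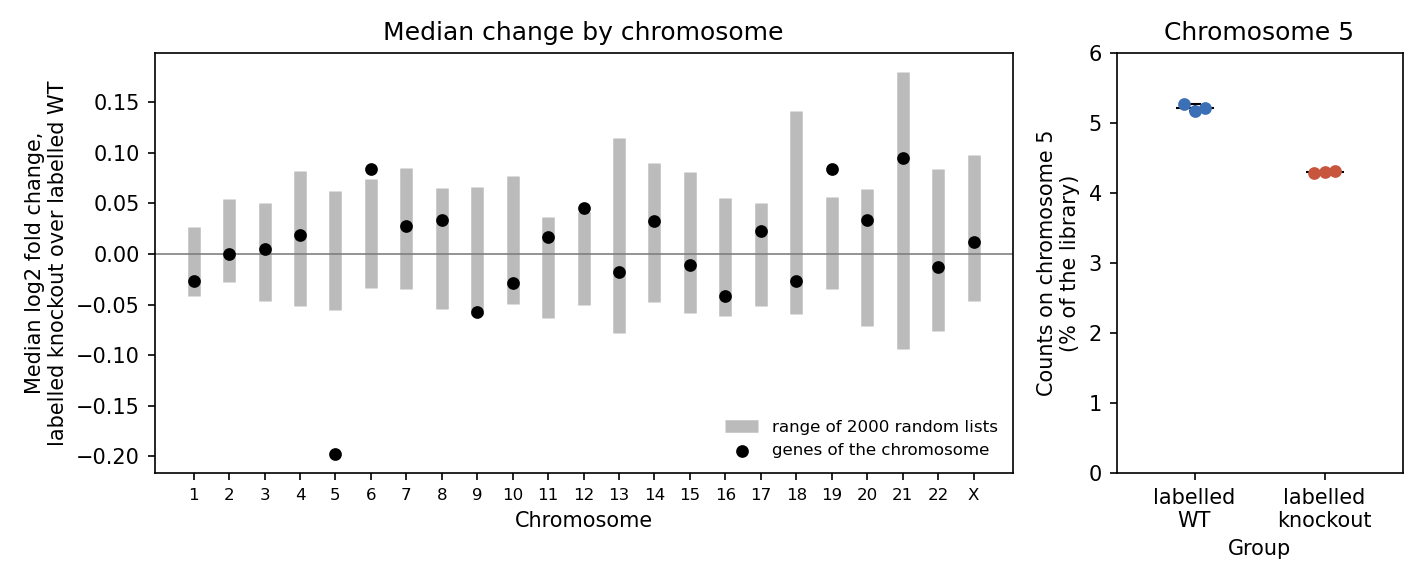
Left, median log2 fold change (labelled knockout over labelled WT) of the tested genes of each chromosome as black points, with grey bars for the range of 2000 random gene lists of the same size and mean expression; chromosome 5, at -0.20, lies below its bar, which ends at -0.05, and chromosomes 6 (0.08), 12 (0.05) and 19 (0.08) lie above theirs. Right, percent of each library's counts on chromosome 5, 1 point per library with the mean and 1 SD, between 5.18% and 5.28% in the libraries labelled WT and between 4.29% and 4.32% in those labelled knockout.

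Genes induced by low oxygen were higher in the libraries labelled knockout. Of 20 hypoxia targets 18 were higher and 2 lower, also adjusted over the list alone (median 0.74, camera adjusted p = 4.46e-06, adjusted p = 0.288 with an estimated correlation). Beside ANGPTL4 and CA9, the prolyl hydroxylase EGLN3 rose (1.74) and NDRG1 went from 256.1 ± 52.6 to 655.9 ± 63.4 CPM (SD, n = 3 each), whereas ADM (-0.86) and VEGFA (-0.22) fell. The libraries labelled WT were uneven for the 4 genes named as higher, with most in WT replicate 2 (NDRG1 counts 5448, 8378 and 5586, EGLN3 counts 708, 1474 and 950). Without WT replicate 2 the list still passed (median 0.75, camera adjusted p = 2.65e-06). Glycolysis genes were 13 higher and 4 lower of 22, also adjusted over the list alone (median 0.16, camera adjusted p = 0.0416, adjusted p = 0.628 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.0725), without WT replicate 3 (0.0547), without KO replicate 1 (0.081) and with the replicate number as a block (0.0678). The glucose transporter SLC2A3 (2.65 ± 0.12, SE) and PFKFB4 (1.82 ± 0.10) rose, while GAPDH and HK2 did not pass the test (-0.01 and -0.03). Cholesterol synthesis genes were 14 higher and 2 lower of 24, also adjusted over the list alone (median 0.17, camera adjusted p = 0.00739, adjusted p = 0.26 with an estimated correlation). TM7SF2 (1.14), INSIG1 (0.84) and MSMO1 (0.71) were among the highest. Fatty acid synthesis genes did not pass camera as a list (5 higher and 4 lower of 13, also adjusted over the list alone, camera adjusted p = 0.591), with the desaturases FADS2 (0.83) and SCD (0.53) higher.

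Targets of the transcriptional coactivator YAP and its partner TEAD were lower in the libraries labelled knockout, 18 of 22 with 0 higher (19 and 0 adjusted over the list alone, median -0.58, camera adjusted p = 2.2e-07, adjusted p = 0.261 with an estimated correlation). ANKRD1 went from 22.8 ± 5.93 to 4.81 ± 0.28 CPM, CTGF from 12.8 ± 2.57 to 3.74 ± 0.464 CPM and CYR61 from 148.7 ± 10.1 to 58.1 ± 1.36 CPM (SD, n = 3 each). Outputs of the MAPK pathway were 10 lower and 4 higher of 19, also adjusted over the list alone (median -0.15, camera adjusted p = 0.0269, adjusted p = 0.302 with an estimated correlation). FOSL1 (-1.38 ± 0.05, SE) and the feedback inhibitor SPRY4 (-1.16 ± 0.09) were lowest. This call was lost with cyclic loess (adjusted p = 0.182), with a stricter filter (0.0651) and with the replicate number as a block (0.0597). ERBB receptors and ligands went both ways, 4 higher and 5 lower of 12, also adjusted over the list alone (camera adjusted p = 0.848). Their median, 0.02, and mean, -0.02, differ in sign. The ligands HBEGF (-1.04) and NRG1 (-0.78) fell and the receptors ERBB3 (0.65) and ERBB2 rose. Integrins, laminins and focal adhesion genes were 15 lower and 7 higher of 24, also adjusted over the list alone (camera adjusted p = 0.0877, but 0.0308 with limma-voom and 0.0487 without chromosome 5), with LAMA3 (-0.74) lower and ITGA5 (0.77) higher. Matrix proteases and their inhibitors were 14 higher and 4 lower of 21, also adjusted over the list alone (median 0.65, camera adjusted p = 0.00273, adjusted p = 0.252 with an estimated correlation). Tissue plasminogen activator, PLAT, went from 207.2 ± 9.81 to 743.3 ± 10.8 CPM and MMP7 from 2.27 ± 0.324 to 17.8 ± 1.32 CPM, and the inhibitors TIMP2 (1.04) and TIMP1 (0.87) rose with them.

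Lists of TGF-beta and BMP targets (6 higher and 5 lower of 15, camera adjusted p = 0.968), Wnt targets (3 and 3 of 9, 0.754) and JAK-STAT signalling (6 and 6 of 20, 7 and 6 adjusted over the list alone, 0.982) did not pass camera. For the first 2 the counts were the same adjusted over the list alone, and for JAK-STAT genes the median, 0.01, and camera's direction, lower, differ. Single members did change: the Wnt target ASCL2 (-0.82) fell, and BHLHE40 (0.87), the Wnt inhibitor NOTUM (1.96) and STAT5A (0.74) rose.

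Interferon-stimulated genes were higher in the libraries labelled knockout, 26 of 34 with 1 lower, also adjusted over the list alone (median 0.43, camera adjusted p = 1.76e-05, adjusted p = 0.467 with an estimated correlation). DDX60 went from 42.8 ± 3.33 to 110.8 ± 1.87 CPM and OASL from 60.3 ± 3.72 to 133.8 ± 3.32 CPM (SD, n = 3 each), RSAD2 (0.85) and ISG15 (0.67) rose, and IFI27 fell (-0.56). MHC class I genes were 11 higher and 3 lower of 16 but missed the threshold as a list (12 and 3 adjusted over the list alone, camera adjusted p = 0.0835), which they passed with limma-voom (0.0253), cyclic loess (0.0158) and without chromosome 5 (0.0153). HLA-B (0.57), with near-identical relatives, and PSMB9 (0.40) were higher and TAP2 (-0.43) lower. Cytokines and NF-kB targets split, 8 higher and 10 lower of 26 (9 and 10 adjusted over the list alone, camera adjusted p = 0.57). CSF3 (-1.38 ± 0.09, SE), IL1B (-1.03 ± 0.05), CXCL8 (-0.98) and IL1A (-0.97) fell, and IL6 (1.59 ± 0.22) and BIRC3 (1.04 ± 0.05) rose.

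Oxidative stress genes driven by NRF2 were lower in the libraries labelled knockout, 13 of 17 with 2 higher, also adjusted over the list alone (median -0.33, camera adjusted p = 0.000724, adjusted p = 0.252 with an estimated correlation). AKR1B10 went from 57.1 ± 1.21 to 10.5 ± 1.09 CPM, and AKR1C1 (-1.21), AKR1C2 (-0.88) and AKR1C3 (-0.53), near-identical genes among which reads can be shared, fell with it. Heat shock genes were 7 lower and 1 higher of 9, also adjusted over the list alone (median -0.35, camera adjusted p = 0.0252, adjusted p = 0.288 with an estimated correlation). HSPH1 (-0.69) and HSPA8 (-0.53) were lowest. This call was lost with cyclic loess (adjusted p = 0.145). Targets of p53 (10 higher and 3 lower of 23, 11 and 4 adjusted over the list alone, camera adjusted p = 0.503), the ATF4 response (7 and 9 of 23, 0.875), the unfolded protein response (6 and 3 of 17, 0.394), immediate early genes (4 and 4 of 13, 0.784) and stem cell genes with drug transporters (5 and 7 of 17, 0.968) did not pass camera as lists, although the unfolded protein response did with cyclic loess (0.0138). The last 4 had the same counts adjusted over the list alone. For the ATF4, immediate early and stem cell lists the median, the mean and camera's direction did not all share a sign. Among their members, PLK3 (-0.96), the drug transporter ABCG2 (-1.56) and JUN (-0.84) fell, and CTH (1.16), HSP90B1 (0.38), SOX2 (1.67) and CD24 (1.38) rose.

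Markers of other cell types were mostly below the expression filter. The lymphoid and myeloid gene LAPTM5 went from 79.2 ± 4.06 CPM in the libraries labelled WT to 30.9 ± 2.12 CPM in those labelled knockout (SD, n = 3 each, log2 fold change -1.36 ± 0.06, SE), while CD14 did not pass (0.42) except adjusted over the list alone, which gave 1 higher and 1 lower of 2. All 4 measured endothelial markers were higher, also adjusted over the list alone: CLDN5 (1.93 ± 0.18, SE), CDH5 (1.53), PECAM1 (0.36) and VWF (1.40). VWF, at 0.720 CPM in the libraries labelled knockout, lost its call without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2, and with cyclic loess. Its log2 fold change ran from 0.94 without WT replicate 2 to 2.26 without WT replicate 1, which held 13 of its counts against 2 and 5 in the other libraries labelled WT. Of 3 fibroblast markers COL1A1 was higher (0.43 ± 0.07, SE), also adjusted over the list alone, and CHGA, the 1 acinar or islet marker measured, did not pass by edgeR (-0.80 ± 0.36, SE, adjusted p = 0.064) but was lower adjusted over the list alone. CHGA also passed as lower under 2 of 15 alternatives, over which its log2 fold change ran from -1.08 to -0.56. These 4 lists had fewer than 5 measured members and were not tested as lists.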

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

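Cyclic loess with limma-trend, limma-trend with TMM factors and the fit without chromosome 5 were chosen after the data were seen. MUC16 stayed higher in the libraries labelled knockout in all 16 alternatives (log2 fold change 1.55 to 1.99), and the 8 highest and 8 lowest genes under the naming rule kept their direction and call in each. Of 154 called genes named by the rule, 7 low or little-changed ones (EPGN, RNF43, ALDH1L2, SPATA18, AXIN2, VWF, MT-ND4L) lost the call under at least 1 alternative. The count of changed genes stayed between 6935 and 8766 except where at least 2-fold was required (1478 genes, 1252 higher and 226 lower). Genes changed at least 2-fold were 602 higher and 92 lower with the stricter filter, which tests fewer genes, 828 and 406 with cyclic loess, and 136 lower with protein-coding genes alone, which leaves out other genes. Limma-trend with TMM factors gave 1192 and 202, so cyclic loess rather than its test moved the split. With upper-quartile factors 59.4% of the called genes were higher, against 50.7%. Lists past the threshold numbered 0 with an estimated correlation, which has few residual degrees of freedom, and 29 with fry, which asks another question. Apart from the estimated correlation, 12 of the 19 lists kept their call under every alternative; mucins, classical and basal-like genes, glycolysis, oxidative phosphorylation, MAPK output and heat shock genes did not, and 5 lists (MUC16 partners, MHC class I, integrins, mitochondrially encoded genes and the unfolded protein response) gained one under an alternative other than fry. The DESeq2 test was not applied to lists, and camera passed 19 lists with DESeq2 size factors and 23 with limma-voom. No called result reversed, while medians of uncalled lists such as Wnt targets (-0.40 to 0.58) and ERBB genes (-0.13 to 0.12) changed sign. Same-numbered libraries did not deviate together (correlations 0.05, 0.02 and -0.07 across genes), so the numbers were not taken to pair; with the replicate block 8442 genes and 16 lists passed, without mucins, glycolysis and MAPK output. In the simulation, where few genes changed and all had the same dispersion, 88% of 2-fold changes were called.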

Other observations

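The gene families, the chromosome comparison, cyclic loess and the tests on MUC16, on parts of chromosome 5, on sense intronic genes and on low counts were chosen after the data were seen. Among 239 gene families defined by a shared symbol stem, 36 passed camera, and none did with an estimated correlation (lowest adjusted p = 0.587). Genes of both ribosomes were lower in the libraries labelled knockout: 37 of 49 genes with the stem RPL, cytosolic large-subunit proteins, were lower and 0 higher (median -0.18, camera adjusted p = 5.75e-05, adjusted p = 0.667 with an estimated correlation), and 32 of 49 with the stem MRPL, their mitochondrial counterparts, were lower and 0 higher (median -0.23, camera adjusted p = 2.8e-05, adjusted p = 0.667 with an estimated correlation). The RPL call was lost with cyclic loess (median -0.07, adjusted p = 0.12, and down to 1.21e-07 with other alternatives), while the MRPL call held in all 14 alternatives. Of 42 genes with the stem RPS, 21 were lower and 3 higher (median -0.14, camera adjusted p = 0.0182, adjusted p = 0.667 with an estimated correlation). A stem is the symbol up to its first digit. RPS therefore holds cytosolic small-subunit proteins but also kinases named after one, so these values are not of the small subunit alone. With the stem MRPS, of mitochondrial small-subunit proteins, 16 of 28 were lower and 0 higher (median -0.21, camera adjusted p = 0.00276, adjusted p = 0.667 with an estimated correlation). All genes over 64 CPM had a median of -0.11, and camera does not match lists on expression level.

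Serine protease families went the other way. Kallikreins were 8 higher and 0 lower of 9 in the libraries labelled knockout (median 0.95, camera adjusted p = 0.00276, adjusted p = 0.587 with an estimated correlation), with KLK13 from 5.13 ± 0.436 to 10.7 ± 0.625 CPM, and genes with the stem PRSS were 8 higher and 0 lower of 9 (median 0.90, camera adjusted p = 0.0048, adjusted p = 0.587 with an estimated correlation), with PRSS22 from 13.4 ± 1.15 to 35.8 ± 2.46 CPM (SD, n = 3 each). Histone genes were 20 higher and 2 lower of 38 (median 0.49, camera adjusted p = 0.000696, adjusted p = 0.587 with an estimated correlation). The share of counts on ribosomal RNA genes was also higher in the libraries labelled knockout, 0.159% ± 0.0097 against 0.133% ± 0.00785, and that on protein-coding genes lower, 98.15% ± 0.0259 against 98.26% ± 0.016 (SD, n = 3 each). HIST1H2AE went from 3.35 ± 0.638 to 9.39 ± 1.24 CPM, and reads can be shared between near-identical histone genes. The protocadherin beta cluster rose, 9 higher and 0 lower of 10 (median 1.14, camera adjusted p = 0.00636, adjusted p = 0.587 with an estimated correlation), at low levels (PCDHB13 from 0.587 ± 0.121 to 1.67 ± 0.315 CPM), although it lies on chromosome 5, whose genes were lower as a whole.

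MUC16 was higher in the libraries labelled knockout. Its 83 tested neighbours within 2 Mb had a median log2 fold change of 0.18 (bootstrap interval 0.01 to 0.32), with 36 higher and 17 lower. That median is too small for a gain of most of this range to account for 1.79. A gain of MUC16 with a few neighbours would leave the median unmoved and is not excluded. ANGPTL4 (3.72), the highest gene under the naming rule, lies within this range. The 740 genes at a like expression level had a median of 0.0663, which argues against a general rise of genes at that level. Exchanged group labels stay open. The lower group held 28.7% of the MUC16 level of the higher. A knockout may remove the protein while the RNA remains, so the level alone cannot decide. The titles of the libraries labelled knockout, T3M4M16, do not say knockout and cannot decide it either. The edit itself is a biological explanation that stays open and was not tested, since reads by exon were not used here.

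Chromosome 5 was lower over its whole length in the libraries labelled knockout, with all 10 of its 10 segments of like gene number below the other chromosomes. That argues against an event in one part of it, and genes of other chromosomes matched on GC content, length and expression had a median of -0.0129 (1000 draws, -0.05 to 0.04), which argues against those properties. Fewer copies of chromosome 5 in the cells labelled knockout is a candidate explanation that these values cannot decide. Its genes were shifted with the same spread as others (ratio of interquartile ranges 1.01, bootstrap interval 0.932 to 1.09). That spread is weak evidence, since the autosomes and X all had interquartile ranges between 0.503 (chromosome 18) and 0.694 (chromosome 19), with 0.582 for chromosome 5. The shift was 0.865-fold relative to the other chromosomes, and the copy number in these cells was not measured. A smaller shift among genes under 4 CPM (-0.14) than over 32 CPM (-0.25) and the rise of the protocadherin cluster do not follow from copy number alone. If copies were lost, the groups may differ by clonal history as well as by MUC16, and the design cannot separate these; DNA would be needed.

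More genes were higher than lower at 2-fold, 1252 against 226. Scaling stays open: the ratio of higher to lower, 5.54 with TMM factors, was 5.37 with DESeq2 size factors and 7.31 with upper-quartile factors, but 2.04 with cyclic loess, between the bounds set for and against it, and 5.90 with the same test and TMM factors. More DNA or unspliced RNA is argued against by the share of counts on sense intronic genes, 0.981 times that in the libraries labelled WT (highest pair of libraries 1.08), although lincRNA (median 0.26) and antisense genes (0.15) had higher medians. Counts too low to show a fall could not be singled out as a cause. The ratio was 1.93 (exact 95% interval 1.00 to 3.88) among genes over 64 CPM, the range tested first. It was 5 (3.11 to 8.41) among genes of 16 to 64 CPM, a range chosen after the first value was seen, where a fall would be measurable. Below that it was 7.07 at 4 to 16 CPM, 7.44 at 1 to 4 CPM and 4.54 under 1 CPM, so it was not largest where counts were lowest. Genes over 64 CPM also had a median log2 fold change of -0.11, which by itself lowers their ratio. Loss of MUC16 or another difference between the cells stays open as an untested biological explanation.

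With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes, 8759 and 1478 at 2-fold, against a highest of 0 and 0 by edgeR in the others (up to 161 at an unadjusted p under 0.05), and with the most lists, 19 against up to 10. Each other split had libraries of both labels on both sides. The difference between the groups thus added to the spread within sides and held gene calls down. The 0 calls therefore do not measure how many genes would pass by chance. The other splits still gave 2 to 10 lists by camera with 0 genes called.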
